A study of Homo sapiens with 8 samples.

How the data were processed

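Gene expression was measured on 8 single-channel arrays, 1 per sample, with total RNA from formalin-fixed, paraffin-embedded skin sections, per the labels. The arrays comprised 5 sebaceous hyperplasia lesions and 3 normal skin samples. Per the labels, every sample came from a different individual, so the replicates are biological and no sample of one group has a partner in the other. Biotin-labelled cDNA was made with a whole-transcript kit, per the labels' protocols. No batch, scan day or RNA quality value is given in the sources used here, so no batch could enter the fits.

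The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA (robust multi-array average), per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a set on the log2 scale. The log2 scale was inferred from RMA and from the range of the values. The RMA version, the software that ran it and any filter before deposit are not given in the sources used here. The median over all rows was 1.53, 1.55, 1.52, 1.55 and 1.54 on sebaceous hyperplasia replicates 1 to 5, and 1.56, 1.67 and 1.66 on normal skin replicates 1 to 3. For arrays, their number limits the precision, and 3 normal skin samples give a coarse estimate of the spread in that group.

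The table held 53617 rows. The platform annotation gave exactly 1 gene symbol for 23871 rows and several for 1842, and 27904 rows are unnamed here. Of the rows with 1 symbol, 22569 were brought to current symbols through their gene identifier in a RefSeq gene table (assembly GRCh38.p14, used for names and gene classes), 733 matched by symbol and 569 kept the annotation's name. A further 56 rows of sex-linked genes were left out because the samples are from people. Where a symbol had several rows (630 symbols), the row with the highest mean over all 8 arrays was used. This left 22341 genes, with no filter on dim rows. No coordinates are given, since the build behind the array's annotation is not given in the sources used here. Rows of small RNA families with near-identical members, such as the 5S ribosomal RNA pseudogenes and several microRNA families, can share signal and are treated as uncertain.

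Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior) on the deposited log2 values, sebaceous hyperplasia minus normal skin, with all 8 arrays in one fit and no covariate. P-values are two-sided, and an adjusted p (Benjamini-Hochberg over all genes tested) under 0.05 counted as passing. A log2 difference of 1 marked 2-fold changes. The errors given with differences are limma's standard errors.

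The 28 gene lists, with 659 entries of which 567 were measured, covered sebaceous gland markers, lipid, steroid and retinoid metabolism, the lysosome, the Hedgehog pathway, cell types of skin, keratinocyte activation, cell division, immediate early genes, ribosomal proteins and the respiratory chain. Genes may stand in more than 1 list. Each list was tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the 28 lists. Beside it stand camera with an estimated correlation, fry, and an exact permutation test of the list mean over the 56 ways to choose 3 of 8 arrays, two-sided, whose smallest possible p is 0.0179. Passing with the preset correlation was called here in 14 lists, and none of these calls held with an estimated correlation. Each list's members were also adjusted over the list alone. Over all genes, 5282 of 22341 had an unadjusted limma p under 0.05. Counts within a list therefore do not show that it exceeds other genes of like signal. The lists were written from general knowledge of skin and not drawn from these samples.

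The genes named in the text follow a rule. It takes the 8 genes with the largest rise and the 8 with the largest fall among those that passed and whose values do not overlap between groups, up to 4 members of each list that passed with the largest difference (or, where none passed, the 2 with the smallest p), and 6 anchors (MC5R, AWAT2, FADS2, PPARG, KRT79 and SQLE). Because small RNA rows took many of these places, the 8 largest rises and falls among protein-coding genes were added after the values were seen. The groups, tests, lists, the rule and the first set of alternatives were fixed before the data were examined.

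The alternatives were each array left out in turn, array medians subtracted, a second quantile normalization, 2 filters on dim genes, array weights, a trended and robust prior, the mean of a symbol's rows, all rows, an unequal-variance test per gene, a 1.2-fold minimum change, the other list tests, and lists without shared genes. After the data were seen, 3 more were added because normal skin replicates 2 and 3 stood apart: normal skin replicate 1 as the only control, each array's signal range (90th percentile minus median) as a covariate, and protein-coding genes alone. In the fit with 1 control array, that lone sample is assumed to vary like the lesions. Its p-values set 1 individual against the lesions, and camera was run there with its preset correlation only. Signal range mainly separates normal skin replicates 2 and 3 from the other arrays. The covariate fit therefore leans on replicate 1 as well, and camera was run in it with the preset correlation only.

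The gene and list tests were first tested on simulated data with the real means and spreads of this comparison. Over 22341 genes, limma recovered 72% of 100 genes changed by a log2 difference of 1 and 98% of 100 genes changed by 3, with 12 false calls. A list of 27 genes raised by 1 came out at 0.98, with an exact permutation p of 0.0179. The simulation gave all 8 arrays the same spread and drew each gene independently. It therefore covers neither arrays that stand apart nor genes that vary together. In it the raised list passed camera with an estimated correlation (adjusted p = 0.000676), which no list did in the real data. The estimated correlation of that list was 0.48 in the real data. To compare a list with other genes of like signal, its median difference was set among 10000 random lists matched on mean expression. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.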

Results

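Expression was profiled on arrays in 5 lesions of sebaceous hyperplasia, a benign enlargement of the oil glands of the skin, and in 3 samples of normal skin from other individuals. All RNA came from archived, formalin-fixed tissue sections, in which RNA is usually fragmented. The comparison asks which genes are higher in tissue rich in sebaceous glands than in normal skin, in a series concerned with the loss of these glands in psoriasis. Values are log2 signals as deposited, and differences are sebaceous hyperplasia minus normal skin on that scale. The 5 lesion arrays resembled each other closely, with Pearson's r between 0.943 and 0.960 across the 22341 genes, which are not independent replicates. Normal skin replicate 1 correlated with the lesions at 0.921 to 0.937. Normal skin replicates 2 and 3 stood apart, at 0.778 to 0.801 with the lesions, 0.808 to 0.818 with replicate 1 and 0.868 with each other. Their signal range, the 90th percentile minus the median over genes, was 1.27 and 1.28, against 1.85 for replicate 1 and 1.88 to 2.08 for the lesions. Each gene group below is therefore also given against normal skin replicate 1 alone, a setting chosen after the data were seen. That setting rests on 1 control sample.

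The average of the sebaceous gland markers was higher in each of the 5 lesions than in any normal skin sample. Over the 27 measured genes of the list, the log2 signal was 5.12 ± 0.30 (SD, n = 5) in lesions and 3.12 ± 1.01 (SD, n = 3) in normal skin, a difference of 1.99 or 3.97-fold (exact permutation test, p = 0.0179, the smallest that 56 splits can give). Of these genes 7 rose. They were DGAT2L6, an acyltransferase of the wax and triacylglycerol family, by 3.61 ± 0.63 (SE, adjusted p = 0.0386), the lipoxygenase ALOX15B by 2.81 ± 0.44, the keratin KRT79 by 2.74 ± 0.38, the fatty acid desaturase FADS2 by 2.24 ± 0.43, PPARG, a nuclear receptor that drives lipid-storing cells, by 2.14 ± 0.39, fatty acid synthase FASN by 1.99 ± 0.34 and the lipid droplet protein CIDEA by 1.61 ± 0.31. With an array left out, KRT79 passed in 3 of the 8 fits and each of the other 6 in only 1. The wax synthase AWAT2 differed by 2.96 ± 0.75 and did not pass over all genes (adjusted p = 0.0703; 0.74 against normal skin replicate 1 alone). The melanocortin receptor MC5R had the same mean in both groups, 2.05 ± 0.38 (SD, n = 5) and 2.05 ± 0.36 (SD, n = 3). Adjusted over the list alone, 25 of the 27 passed. camera gave the list an adjusted p of 5.19e-15 with its preset correlation, and an adjusted p = 0.202 with an estimated correlation. The list mean was 4.28 in normal skin replicate 1, 2.43 in replicate 2 and 2.66 in replicate 3. With replicate 1 as the only control the difference was 0.83 and the 5 lesions still lay above it, though this rests on 1 sample. KRT79 differed by 1.83 there. With each array's signal range as a covariate, also chosen after the data were seen, the list differed by 0.51 (camera with its preset correlation, adjusted p = 2.01e-05). Signal range mainly sets normal skin replicates 2 and 3 apart, so this fit leans on replicate 1 and is not a separate check.

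**Figure D1:**
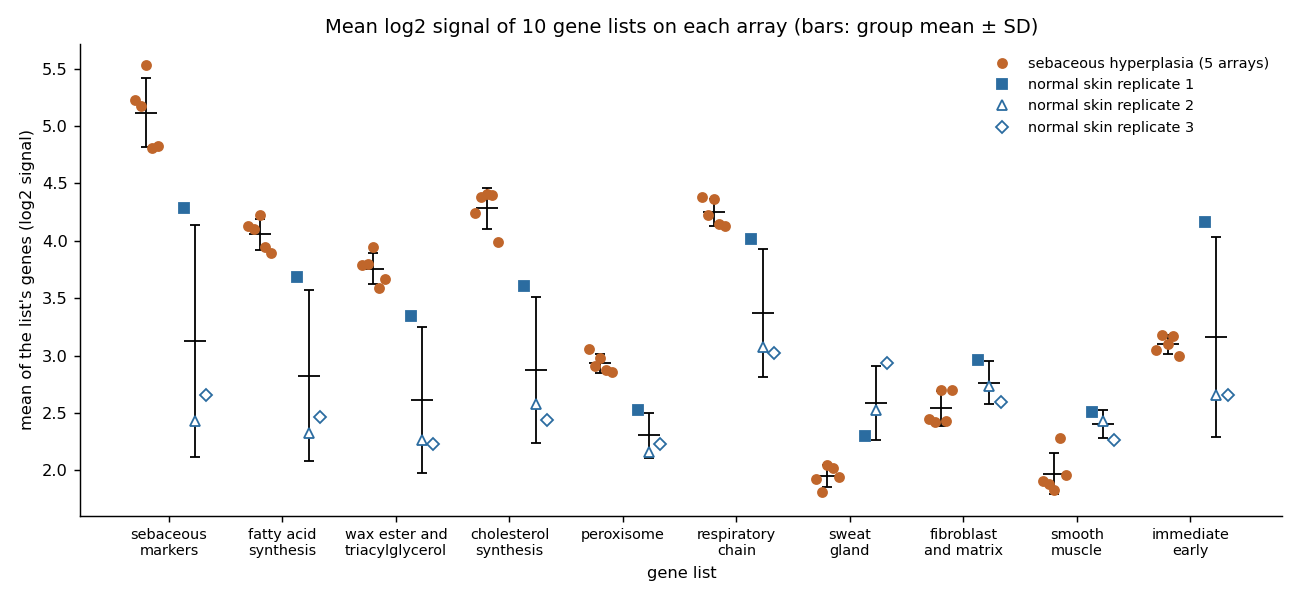
Mean log2 signal of 10 gene lists on each of the 8 arrays. Points are arrays and bars are group means with SD. For sebaceous markers the 5 lesions lie above all 3 normal skin samples, of which replicate 1 (4.28) is closest to them.

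**Figure D2:**
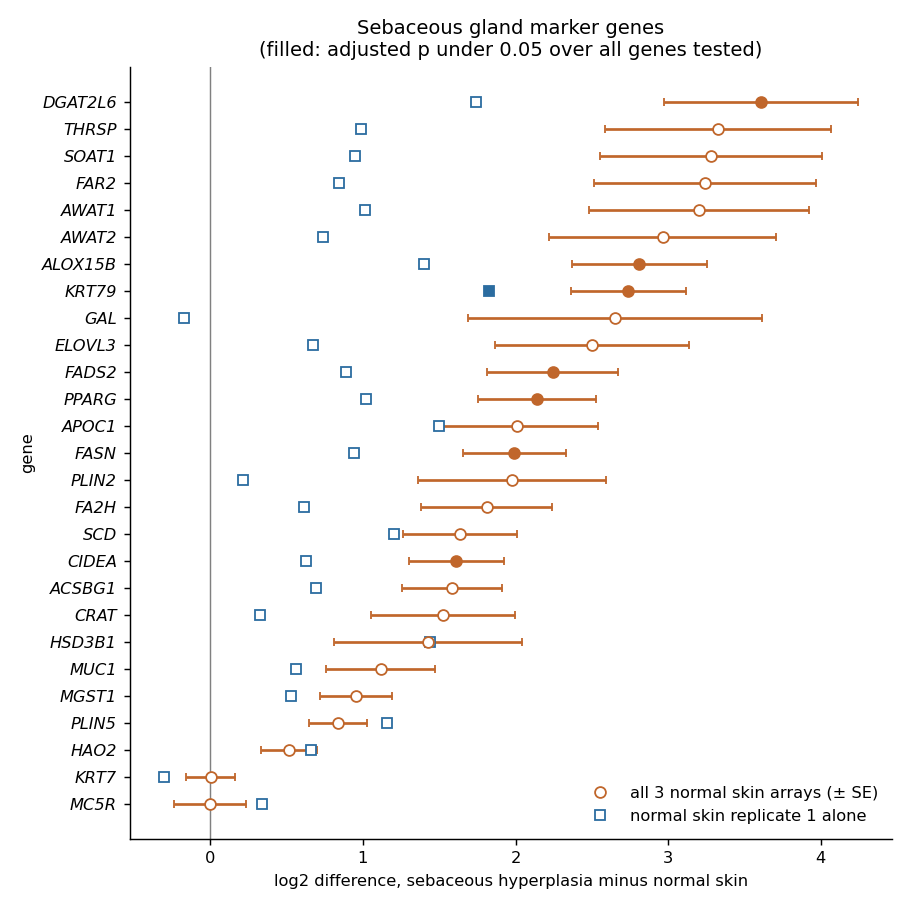
Log2 difference of the 27 measured sebaceous gland markers, with the SE against all 3 normal skin arrays (circles) and against normal skin replicate 1 alone (squares). Filled symbols passed over all genes tested. DGAT2L6 differed by 3.61 against all 3 arrays and by 1.74 against replicate 1.

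Lipid synthesis lists were higher on average in the lesions, with 24 of 27 and 21 of 24 members positive in the first pair. In the list of fatty acid synthesis, elongation and desaturation, 3 of 27 genes rose, namely FADS2, FASN and ACLY, which makes cytosolic acetyl-CoA (2.10 ± 0.28 SE, adjusted p = 0.0180), and 14 passed when adjusted over the list alone. Its mean differed by 1.23 (camera adjusted p = 8.33e-08, and adjusted p = 0.217 with an estimated correlation). With normal skin replicate 1 alone the difference was 0.38, and with signal range as a covariate it was 0.19 and did not pass (camera adjusted p = 0.0830). In the list of wax ester and triacylglycerol synthesis and lipid droplets, 3 of 24 genes rose, DGAT2L6, CIDEA and the monoacylglycerol acyltransferase MOGAT1 (2.16 ± 0.41 SE), and 12 passed adjusted over the list alone. Its mean differed by 1.15 (adjusted p = 2.39e-06, and adjusted p = 0.202 with an estimated correlation) and by 0.41 against replicate 1 alone. Both of these lists share genes with the sebaceous markers.

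In cholesterol biosynthesis 4 of 18 genes rose and 15 passed adjusted over the list alone. ACAT2, which condenses acetyl-CoA at the start of the pathway, rose by 2.48 ± 0.35 (SE), the sterol dehydrogenase NSDHL by 1.93 ± 0.38, farnesyl diphosphate synthase FDPS by 1.78 ± 0.25 and the decarboxylase MVD by 1.09 ± 0.19. Squalene epoxidase SQLE differed by 0.63 ± 0.22 and did not pass (adjusted p = 0.135). The list mean differed by 1.41 (camera adjusted p = 5.98e-10, and adjusted p = 0.202 with an estimated correlation), and by 0.68 without normal skin replicates 2 and 3. Peroxisome genes differed by 0.63 on average (adjusted p = 1.47e-07, and adjusted p = 0.184 with an estimated correlation). Here catalase CAT rose by 0.89 ± 0.17 and the carnitine acyltransferase CROT by 0.84 ± 0.15, 2 of 29 genes, with 16 adjusted over the list alone. The peroxisome difference against replicate 1 alone was 0.40, and catalase, at 1.11, and CROT, at 0.91, kept their size there without passing.

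Among lysosomal genes the membrane protein LAMP1 rose by 1.47 ± 0.20 (SE, adjusted p = 0.0193), 1 of 22, with 9 adjusted over the list alone. The list mean differed by 0.52 (camera adjusted p = 0.000150, and adjusted p = 0.227 with an estimated correlation) and by 0.21 without normal skin replicates 2 and 3. With signal range as a covariate it differed by 0.08 and did not pass (adjusted p = 0.443), and its median difference lay at percentile 71.9 of expression-matched random lists. Steroid and androgen metabolism did not pass as a list (mean 0.22, median -0.05, camera adjusted p = 0.875, 0.11 against replicate 1 alone). Within it SRD5A1, a reductase that makes dihydrotestosterone, rose by 1.87 ± 0.29 (adjusted p = 0.0290), 1 of 23 genes, with 3 adjusted over the list alone. Retinoid metabolism and binding did not pass either (mean 0.12, adjusted p = 0.770, 0.09 against replicate 1 alone), though the short-chain dehydrogenase DHRS9 rose by 0.70 ± 0.13, 1 of 23 genes, with 2 adjusted over the list alone. No Hedgehog pathway gene of 13 passed, and the list's mean was 0.00, its median -0.06 and its camera direction downward (adjusted p = 0.762), with -0.12 against replicate 1 alone. BOC, a co-receptor, differed by 0.47 ± 0.13 (adjusted p = 0.0858) and the transcription factor GLI1 by -0.29 ± 0.17 (adjusted p = 0.325).

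Sweat gland and smooth muscle markers were lower on average in the lesions. Dermcidin, DCD, an antimicrobial peptide of eccrine sweat, fell by 4.66 ± 0.86 (SE, adjusted p = 0.0413). It was 1.15 ± 0.11 (SD, n = 5) in lesions and 2.95, 7.03 and 7.45 in normal skin replicates 1 to 3, and it also passed against replicate 1 alone (-1.80, adjusted p = 0.00726), but in only 1 of the 8 fits with an array left out (highest adjusted p = 0.161). The sweat gland list differed by -0.64 (1 of 17 fell, 5 adjusted over the list alone, camera adjusted p = 0.00194, and adjusted p = 0.202 with an estimated correlation) and by -0.35 against replicate 1 alone. Its median difference was smaller, at -0.29. After DCD the most negative members were PIP (-2.26) and SCGB2A2 (-1.54), which did not pass over all genes. In the other direction went 4 members, among them CA6 (1.25 ± 0.51) and MUCL1 (0.12 ± 0.39), also without passing. In the smooth muscle list 2 of 14 genes fell, the smooth muscle myosin MYH11 by 1.28 ± 0.24 and the smooth muscle actin ACTA2 by 0.98 ± 0.20, with 6 adjusted over the list alone. Its mean differed by -0.43 (adjusted p = 0.000374, and adjusted p = 0.203 with an estimated correlation) and by -0.54 against replicate 1 alone. By exact permutation it did not pass (adjusted p = 0.0769), with lesion replicate 4 (2.28) above normal skin replicate 3 (2.27).

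Fibroblast and dermal matrix genes differed by -0.23 on average (camera adjusted p = 0.00300, and adjusted p = 0.244 with an estimated correlation) and by -0.43 against normal skin replicate 1 alone. None of the 24 passed over all genes, and 1 higher and 5 lower adjusted over the list alone. The collagen COL1A1 differed by -0.70 ± 0.15 (SE, adjusted p = 0.0554) and the microfibril gene MFAP5 by -0.84 ± 0.20. Without normal skin replicate 1 the list differed by -0.13 and no longer passed (adjusted p = 0.126), nor did it pass by fry (adjusted p = 0.0676) or exact permutation (adjusted p = 0.150), and 3 of 5 lesions lay below all normal skin samples. The T and B lymphocyte list differed by -0.19 (adjusted p = 0.0151, and adjusted p = 0.202 with an estimated correlation; -0.21 against replicate 1 alone), with CD5 at -0.63 ± 0.17 and MZB1 at -0.73 ± 0.22, neither of which passed. Without replicate 1 it differed by -0.17 (adjusted p = 0.0865). Its median difference lay at percentile 9.05 of expression-matched random lists against all controls and 0.73 against replicate 1 alone. The endothelial list differed by -0.18 (adjusted p = 0.0300, and adjusted p = 0.202 with an estimated correlation; -0.17 against replicate 1 alone). It no longer passed without lesion replicate 2 (-0.18), normal skin replicate 1 (-0.19) or normal skin replicate 2 (-0.13), and TEK (-0.37 ± 0.10) and ERG (-0.73 ± 0.22) did not pass. Schwann cell and nerve genes differed by -0.22 (adjusted p = 0.0339, and adjusted p = 0.217 with an estimated correlation). That call ended without lesion replicate 1 (-0.21) or 3 (-0.21), without normal skin replicate 1 (-0.24) or 3 (-0.18), with replicate 1 as the only control (-0.18), with signal range as a covariate (-0.13, adjusted p = 0.556), without the dimmest 25% of genes (-0.18, adjusted p = 0.0995) and by exact permutation (adjusted p = 0.125). SCN7A (-0.30 ± 0.11) and MBP (-0.31 ± 0.11) did not pass. No gene of the lymphocyte, endothelial and Schwann cell lists passed adjusted over the list alone.

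**Figure D3:**
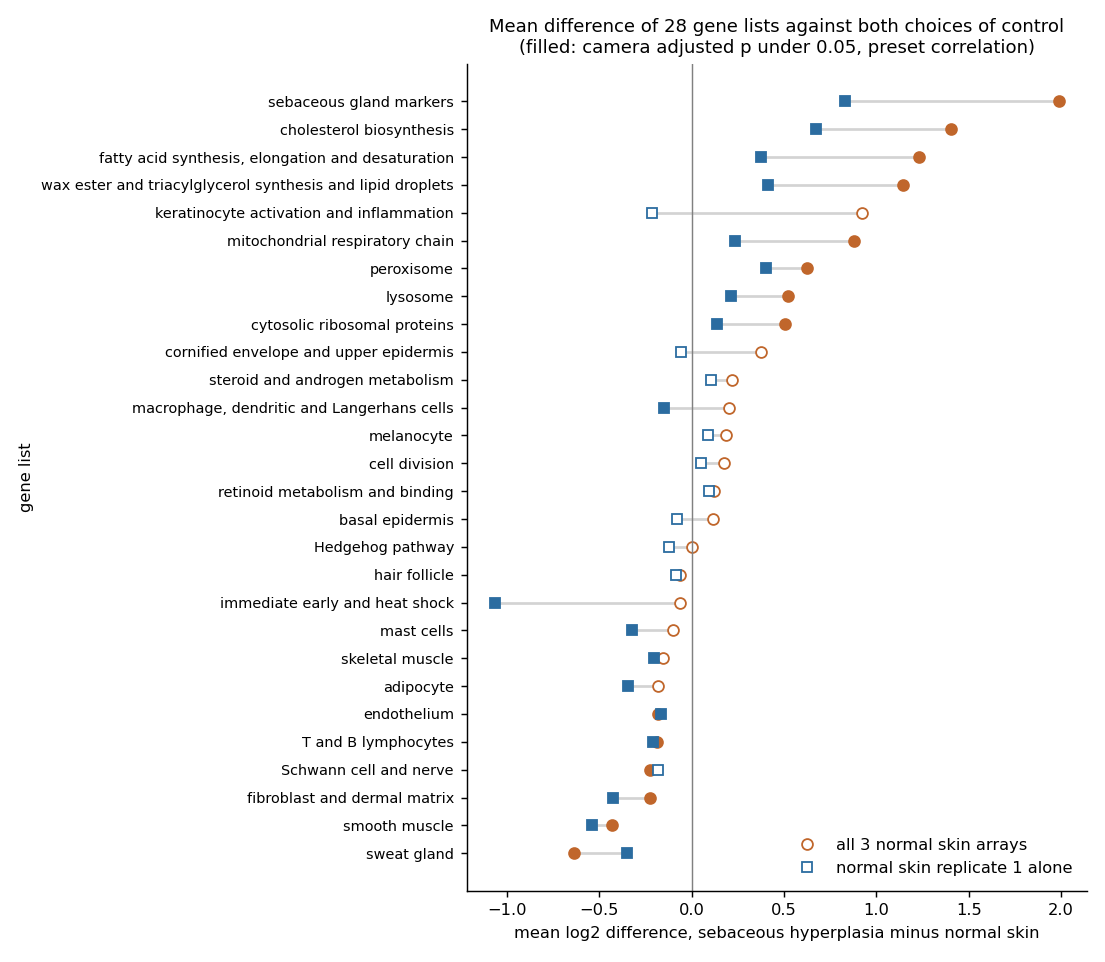
Mean log2 difference of the 28 gene lists against all 3 normal skin arrays (circles) and against normal skin replicate 1 alone (squares). Filled symbols passed camera with its preset correlation. The sebaceous gland marker list has the largest positive difference in both, 1.99 and 0.83, while immediate early genes lie at -0.06 and -1.07.

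The epidermal lists did not pass, and no member of either passed over all genes. Cornified envelope genes differed by 0.37 on average (camera adjusted p = 0.0621) and by -0.06 against normal skin replicate 1 alone, with CASP14 at 2.01 ± 0.49 (SE) and KLK7 at 0.86 ± 0.24. The list passed without lesion replicate 4 (0.44) or 5 (0.41), without normal skin replicate 1 (0.59) or 2 (0.35) and with array weights (0.46, adjusted p = 0.0296). With an estimated correlation, run on all 8 arrays only, it had an adjusted p = 0.588. Its median difference of 0.16 against all controls lay at percentile 0.35 of expression-matched random lists, and at 5.84 against replicate 1 alone. These passes thus do not show a rise beyond that of other genes of like signal. Against replicate 1 alone CASP14 differed by 0.57. Basal epidermal genes differed by 0.11 (adjusted p = 0.406; -0.08 against replicate 1 alone), with KRT5 at 0.91 ± 0.20 and KRT15 at 0.23 ± 0.14 (-0.09 against replicate 1 alone), and 1 of 11 passed adjusted over the list alone. The hair follicle list differed by -0.06 (camera adjusted p = 0.275, and adjusted p = 0.588 with an estimated correlation) and by -0.09 against replicate 1 alone. At the preset correlation it passed with genes above the median only (-0.14, adjusted p = 0.0168). PADI3 differed by -0.39 ± 0.14 and LGR5 by -0.75 ± 0.19.

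Other cell type lists also did not pass, and no member passed over all genes or adjusted over the list alone. With an estimated correlation, run on all 8 arrays only, the adjusted p was 0.517 for adipocytes, 0.203 for skeletal muscle, 0.604 for macrophages and related cells and 0.637 for mast cells. Adipocyte genes differed by -0.18 (camera adjusted p = 0.275), with LIPE at -0.38 ± 0.12 (SE) and ADIPOQ at -0.55 ± 0.18. They passed without normal skin replicate 3 (-0.29), and differed by -0.35 against replicate 1 alone. The list mean was 1.73 ± 0.04 (SD, n = 5) in lesions and 2.08, 1.965 and 1.695 in normal skin replicates 1 to 3. Replicate 3 thus lay below the lesion mean. Skeletal muscle genes differed by -0.15 (adjusted p = 0.0754), with TNNC1 at -0.69 ± 0.18 and TNNT3 at -0.74 ± 0.27. They passed without lesion replicate 3 (-0.16), without normal skin replicate 3 (-0.18) and against replicate 1 alone (-0.20, adjusted p = 0.0212). They also passed by fry (adjusted p = 0.0330), by exact permutation (adjusted p = 0.0455, 5 of 5 lesions below all normal skin samples) and with dim genes left out (adjusted p = 0.0297 above the median). Their median difference lay at percentile 21.13 of expression-matched random lists against all controls and 11.15 against replicate 1 alone. They thus did not stand out from other genes of like signal. Macrophage, dendritic and Langerhans cell genes differed by 0.20 (adjusted p = 0.351) with CD207 at 0.66 ± 0.24 and MRC1 at 0.54 ± 0.15, and their direction turned against replicate 1 alone (-0.15, adjusted p = 0.0450). Mast cell genes differed by -0.10 (camera adjusted p = 0.572), with CMA1 at -0.34 ± 0.24 and HPGDS at -0.40 ± 0.22. The list differed by -0.32 against replicate 1 alone and by -0.40 with signal range as a covariate (camera adjusted p = 0.0165). Its mean was 1.713 in lesions and 2.035, 1.711 and 1.702 in normal skin replicates 1 to 3. The negative difference thus rested on replicate 1. Melanocyte genes differed by 0.19 (adjusted p = 0.351; 0.09 against replicate 1 alone), with TYRP1 at 1.11 ± 0.32 and TYR at 0.40 ± 0.19.

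Respiratory chain genes were higher in the lesions, by 0.88 on average (camera adjusted p = 1.27e-11, and adjusted p = 0.203 with an estimated correlation), and by 0.23 against normal skin replicate 1 alone. SDHD, a subunit of succinate dehydrogenase, rose by 1.10 ± 0.11 (SE, adjusted p = 0.00602). It was 4.04 ± 0.03 (SD, n = 3) in normal skin, and it passed with each array left out in turn but not against replicate 1 alone (1.10, adjusted p = 0.0544). It was the only 1 of 33 genes to pass, and 24 passed adjusted over the list alone. Cytosolic ribosomal protein genes differed by 0.50 (adjusted p = 2.31e-07, and adjusted p = 0.217 with an estimated correlation) and by 0.14 against replicate 1 alone. None of the 32 passed over all genes and 12 adjusted over the list alone, with RPL37 at 1.21 ± 0.26 and RPS6 at 0.97 ± 0.20. With signal range as a covariate neither list passed, at 0.07 for the respiratory chain (adjusted p = 0.399) and 0.04 for ribosomal proteins (adjusted p = 0.524). After a second quantile normalization the ribosomal list differed by 0.23 and did not pass (adjusted p = 0.185), nor did it by exact permutation (adjusted p = 0.0769).

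Keratinocyte activation and inflammation genes did not pass as a list. Their mean differed by 0.92 and their median by 0.06 (camera adjusted p = 0.292), with -0.21 against normal skin replicate 1 alone. SERPINB3 differed by 4.15 ± 1.11 (SE, adjusted p = 0.0772) and by 0.65 against replicate 1 alone, with 5.82, 0.81 and 0.32 in normal skin replicates 1 to 3. The interleukin-36 antagonist IL36RN differed by 0.62 ± 0.17, and 2 of 20 genes passed adjusted over the list alone. Cell division genes differed by 0.17 (camera adjusted p = 0.0844, and adjusted p = 0.386 with an estimated correlation) and by 0.05 against replicate 1 alone. None passed, with TYMS at 0.95 ± 0.30 and PCNA at 0.56 ± 0.19. At the preset correlation the list passed without lesion replicate 4 (0.20). Immediate early and heat shock genes differed by -0.06 against all 3 normal skin arrays (adjusted p = 0.785), with HSPH1 at 0.59 ± 0.30 and ATF3 at -0.42 ± 0.21, none passing. With an estimated correlation the list had an adjusted p = 0.914, which was not run for the settings that follow. Their list mean was 4.16 in normal skin replicate 1, 2.66 in replicates 2 and 3 and 3.10 ± 0.08 (SD, n = 5) in lesions. The difference was -1.07 against replicate 1 alone (camera with its preset correlation, adjusted p = 4.95e-12) and 0.44 without it (adjusted p = 0.0219), and with signal range as a covariate it was -1.17 (adjusted p = 2.40e-10). HSPH1 turned to -0.07 against replicate 1 alone.

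The protein-coding genes with the largest rises, 5 named by the rule and 3 added after the values were seen, were PNLIPRP3, a member of the pancreatic lipase family (3.69 ± 0.34 SE, adjusted p = 0.00534), DGAT2L6, the zinc finger gene ZNF675 (3.37 ± 0.61), GK5, of the glycerol kinase family (3.17 ± 0.55), PIGY (3.01 ± 0.51), PM20D1 (3.00 ± 0.52), SECISBP2L (2.97 ± 0.57) and APMAP (2.94 ± 0.42). PNLIPRP3 was 6.63 ± 0.20 (SD, n = 5) in lesions and 2.94 ± 0.92 (SD, n = 3) in normal skin. It passed with each array left out in turn and against normal skin replicate 1 alone (3.15, adjusted p = 0.00179). The other 7 did not pass against replicate 1 alone, where their differences were between 1.15 for SECISBP2L and 2.27 for ZNF675. The small RNA genes VTRNA1-1 (3.73 ± 0.42) and SNORD93 (3.59 ± 0.33) and the pseudogene HNRNPA1P33 (3.33 ± 0.50) were also among the 8 largest rises. SNORD93 passed with each array left out in turn and against replicate 1 alone (3.86, adjusted p = 0.0299).

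Among the 8 largest falls only DCD codes for a protein. The others were the 5S ribosomal RNA pseudogenes RN5S153 (-6.37 ± 0.70 SE) and RN5S191 (-2.73 ± 0.25), the microRNA genes MIR548M (-4.01 ± 0.74), MIR548A2 (-2.41 ± 0.33), MIR1260A (-2.12 ± 0.15, adjusted p = 0.00340) and MIR4300 (-1.91 ± 0.38), and SNORD113-3 (-2.29 ± 0.39). RN5S153, RN5S191, MIR1260A and MIR4300 also passed against normal skin replicate 1 alone. These rows measure short or multi-copy RNAs and their levels are uncertain. The protein-coding falls added after the values were seen were CLEC3B (-1.69 ± 0.29), the mucin-like gene MUCL3 (-1.42 ± 0.17), the stromal cell marker CD248 (-1.40 ± 0.21), MYH11, IFNL3 (-1.20 ± 0.23), ACTA2 and FAM170A (-0.97 ± 0.18), none of which passed against replicate 1 alone. For MUCL3 the mean of all its rows differed by -0.60 and did not pass.

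Over all 22341 genes, 296 were higher and 68 lower in sebaceous hyperplasia by limma at adjusted p under 0.05, and 218 and 31 of these changed at least 2-fold. Of the higher genes 261 were protein-coding and 19 small RNAs, and of the lower genes 24 were protein-coding and 29 small RNAs. The groups did not overlap in 3224 genes, 14.4%, where chance gives 3.57% if all arrays are interchangeable. The normal skin arrays of low signal range stood apart, so that assumption is not met. The share therefore cannot separate a lesion difference from the effect of those arrays. By camera with its preset correlation, 8 lists were higher and 6 lower, and by its estimated correlation none were.

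The counts depended on the arrays. Without normal skin replicate 1, 2936 genes were higher and 1307 lower; without replicate 2 these were 9 and 4, without replicate 3 29 and 18, and without any 1 lesion 27 to 76 and 8 to 18. With replicate 1 as the only control 16 were higher and 53 lower, and after a second quantile normalization 83 and 57. Of the 44 named genes that passed, 5 passed in all 8 fits with an array left out, PNLIPRP3, SNORD93, SDHD, MIR1260A and RN5S191, and VTRNA1-1, RN5S153 and MUCL3 passed in 7. The remaining 36 passed in 4 or fewer.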

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

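The comparisons with expression-matched lists and tissue compartments and the signal range test were chosen after the results were seen, while the counts over other splits of the arrays were set before. Among 109 named genes and lists, 5 had 1 lesion far from the other 4, where chance gives about 5.4, measured as that lesion's gap to its neighbour over the whole range of the group. MYH11 was 2.55 in lesion replicate 4 and 1.59 to 1.75 in the others (0.836 of the range), and the smooth muscle list was 2.28 there and 1.83 to 1.96 elsewhere (0.722). IL36RN was 2.54 in lesion replicate 1 against 1.76 to 1.99 (0.712). HSPH1 was 4.81 in the same replicate against 3.73 to 4.04 (0.714). Schwann cell and nerve genes averaged 1.96 in lesion replicate 2 against 1.69 to 1.75 (0.761).

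Normal skin replicates 2 and 3 stood apart. A lower signal range alike for all genes of like signal is argued against as the whole difference, though only weakly. In replicates 2 and 3 minus replicate 1, 7 of the 28 lists lay outside the central 95% of expression-matched lists. Chance gives 1.4 for independent genes. Genes of 1 list vary together and some stand in more than 1 list, which makes such values more frequent. That 86.9% of the tenth of genes with the highest lesion signal were lower on these arrays than in replicate 1 restates their lower range and decides nothing about its source, so a part played by it stays open. Less sebaceous tissue as the whole difference was first tested with the keratinocyte activation and inflammation list. Its mean was 3.52 in replicate 1, and 1.783 and 1.852 in replicates 2 and 3. Its median difference lay at percentile 28.92 of the expression-matched lists. A median does not register large differences in a minority of members, so this test could not decide. That test was then replaced by the immediate early and heat shock list, picked from the table of all 28 lists with their results in view; its median was lower in these samples than in replicate 1 (-1.30, percentile 0), although the lesions were also lower than replicate 1. Picked in this way, the second value weighs little and may reflect replicate 1 instead, so less sebaceous tissue stays open, as do RNA preservation, body site and sample handling, which were not tested.

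Sebaceous gland markers were higher in lesions. The low signal range of normal skin replicates 2 and 3 as the whole cause is argued against, though only weakly. Against replicate 1 alone the list's median difference of 0.85 lay at percentile 100 of the expression-matched lists. That comparison rests on 1 control sample. The random lists were drawn gene by gene, while genes of this list vary together, which makes high percentiles more frequent. A larger share of sebaceous tissue in the lesion sections is a candidate explanation, given by the lesions' diagnosis itself. Against replicate 1 alone, 5 of the 5 lists of fibroblasts, smooth muscle, sweat glands, endothelium and adipocytes were lower on average in lesions. Replicate 1 was the highest normal skin sample for fibroblasts (2.965), smooth muscle (2.512) and adipocytes (2.08). Against it the cornified envelope (-0.06), basal epidermal (-0.08) and hair follicle (-0.09) lists were also lower, and the melanocyte list (0.09) was higher. The count of compartment lists therefore decides little about the sebaceous share. Whether gland cells also express these genes at another level per cell was not tested in bulk tissue.

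Ribosomal protein and respiratory chain lists were higher in lesions. For both lists the low signal range of normal skin replicates 2 and 3 may be a source. Against replicate 1 alone, the respiratory chain lay at percentile 92.05 of expression-matched lists and the ribosomal proteins at 77.5. Neither stood out there from other genes of like signal. Against all 3 controls these percentiles were 97.8 and 44.75. The list mean was above replicate 1 in 5 of 5 lesions for the respiratory chain and in 4 of 5 for ribosomal proteins. A higher content of these transcripts in gland-rich tissue stays open.

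Of the 56 splits of the 8 arrays into 5 and 3, only the real one gave as many genes higher (296, highest other split 0) or lower (68, highest other 1). The same held for genes at least 2-fold higher (218, highest other 0) or at least 2-fold lower (31, highest other 1). As 1 of 56 is the smallest share possible, chance assignment is unlikely for these counts but not excluded. The counts come from the same fit and are not independent. This says nothing on signal range. Among the 6 splits that kept normal skin replicates 2 and 3 together in the group of 3, only the real one gave as many genes in either direction. That follows from the result over all 56 splits, and 1 of 6 is too large a share to decide anything. The counts of lists are different. Here 8 of the 56 splits gave 8 or more lists higher (highest other 12) and 20 gave 6 or more lower (highest other 11). Chance assignment may therefore account for the number of lists.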

How the results depend on the processing

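The settings with normal skin replicate 1 as the only control, with signal range as a covariate and with protein-coding genes alone were chosen after the data were seen. The sebaceous marker shift (1.99) stayed positive in all settings run, from 1.64 to 2.57 with 1 array left out, was 0.51 with signal range as a covariate, and was 0.83 against normal skin replicate 1 alone, where 6 splits cannot give an exact permutation p under 0.167. With 1 array left out the count of genes higher ran from 9 to 2936 and lower from 4 to 1307, at least 2-fold higher from 9 to 1648 and at least 2-fold lower from 4 to 288, and lists higher from 8 to 10 and lower from 2 to 7. Fewer arrays lower the power, and the high counts came without normal skin replicate 1, which leaves the 2 arrays of low signal range as controls. The following give genes higher, lower, at least 2-fold higher and at least 2-fold lower where these moved by over 1.5 times from 296, 68, 218 and 31. A second quantile normalization gave 83 higher and 57 at least 2-fold higher. Testing fewer, brighter genes gave 735, 104, 513 and 57 (above the median) and 481 higher and 340 at least 2-fold higher (above the lowest 25%). Array weights, which gave normal skin replicate 1 the lowest weight (0.375), called 1605, 462, 1102 and 164. A trended and robust prior gave 187 higher. All rows gave 195 lower, 337 at least 2-fold higher and 120 at least 2-fold lower. The unequal-variance test gave 2, 1, 1 and 1, with 2524 genes at an unadjusted p under 0.05. A 1.2-fold minimum change gave 42, 8, 39 and 8. Replicate 1 as the only control gave 16 higher, 16 at least 2-fold higher and 53 at least 2-fold lower, with 10 lists lower; 21 of its 69 calls were shared with the fit on all controls, which holds the same lesions and replicate 1, so shared signs carry little weight. Signal range as a covariate, which takes up much of the group difference, gave 1, 5, 1 and 5, with 4 lists higher; the fatty acid (0.19), lysosome (0.08), ribosomal (0.04), respiratory chain (0.07), endothelial (-0.19), lymphocyte (-0.17) and Schwann cell (-0.13) lists no longer passed, while the mast cell (-0.40) and immediate early (-1.17) lists did. Protein-coding genes alone gave 457 higher and 10 at least 2-fold lower. With an estimated correlation 0 lists were higher and 0 lower by camera, against 8 and 6 by fry and 7 and 4 by exact permutation. Immediate early genes (-0.06) reversed without normal skin replicate 1 (0.44; -0.31 without replicate 2 or 3), and macrophage, dendritic and Langerhans cell genes reversed against it alone (-0.15); the cause was not tested beyond the values per array. Of the 28 lists, 28 kept their call with array medians subtracted and 27 after a second quantile normalization; of 81 named genes these were 80 and 63. No paired analysis was possible because the samples came from separate individuals. The signal over background of single rows is not given in the sources used here, so dim rows could be set apart by their mean signal alone (481 genes higher without the lowest 25%).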

Other observations

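The gene sets and tests in this part were chosen after the data were seen. With normal skin replicate 1 as the only control, 53 genes were lower in the lesions, among them microRNA and 5S ribosomal RNA pseudogene entries. Protein-coding examples, picked after their values were seen, are the nuclear receptor NR4A2 (-3.48, limma adjusted p = 0.00179), the transcription factor FOSB (-3.19), the matrix protein THBS1 (-3.29), the growth factor FGF7 (-3.22), CCN2 (-2.54), the chemokine CXCL10 (-3.03) and the cytokine IL6 (-1.57). The fatty acid binding protein FABP4, high in fat cells and small vessels, was also lower (-2.70). None of these passed against all 3 normal skin arrays, so they mark that 1 sample against the lesions and not normal skin as a group.

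Past the threshold both against all 3 controls and against replicate 1 alone, fits that share the lesions and replicate 1, were 12 genes higher and 9 lower. The protein-coding ones were PNLIPRP3, KRT79, ISOC1 (2.18 ± 0.27 SE against all controls and 1.47 against replicate 1 alone), LYST (1.96 ± 0.25 and 1.18), BRK1 (1.93 ± 0.20 and 1.41) and NUDT4B (1.36 ± 0.15 and 1.37) among the higher genes, and DCD among the lower. Small RNAs went both ways, higher for SNORD93, SNORD104 (2.69 ± 0.49 and 3.07) and SCARNA20 (2.07 ± 0.19 and 2.15), and lower for SNORD113-5 (-1.19 ± 0.12 and -1.16). Past the threshold in every fit with an array left out were 7 genes higher and 4 lower, among them TMT1A (1.63 ± 0.15) and FERMT1 (1.54 ± 0.15).

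Genes of the pentose phosphate pathway, which supplies NADPH for lipid synthesis, were looked at after values of some of them were seen among the calls. All 5 measured genes were higher in lesions, by 0.63 on average (exact permutation p = 0.0179, the smallest possible) and by 0.55 against normal skin replicate 1 alone, above which all 5 lesions lay. PGD rose by 1.15 ± 0.13 (SE, limma adjusted p = 0.00916) and TKT by 0.98 ± 0.11 (adjusted p = 0.00916), with 1.07 and 0.90 against replicate 1 alone. TALDO1 (0.51 ± 0.16), PGLS (0.32 ± 0.13) and RPIA (0.20 ± 0.13) did not pass. Since the set was chosen after the results were seen, the permutation p does not test a joint rise.

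Small RNA genes stood out among the lower calls, and the following count restates that. They made up 8.65% of the genes tested, 42.6% of the lower calls and 6.42% of the higher calls, an odds ratio of 10.7 between lower and higher calls (95% interval 5.26 to 22.4, Fisher's exact test, p = 2.30e-12). Genes of one family can share signal, which was not checked here. The calls may therefore not be independent, and this p cannot be taken at its value. The number of genes lower itself ran from 4 to 1307 with 1 array left out.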
